A study of Drosophila melanogaster with 12 samples.

How the data were processed

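Gene expression was measured in testes of 4 genotypes with 3 biological replicates each, on 12 Affymetrix Drosophila Genome 2.0 arrays, and groups were taken from the genotypes and replicate numbers in the labels. Per the series' design text, total RNA was extracted from pools of testes with TRIzol and treated with DNase, and scanner files were exported from the Affymetrix software and normalized with RMA in Bioconductor. Per the submitters' processing notes, MAS5, RMA and limma were used, with versions not given in the sources used here. The values deposited by the authors are linear probe-set intensities, 1 column per array; whether MAS5 gave them or RMA with its log2 values turned back is not stated, so their background correction is not known, and the compression of dim or bright probe sets that each method brings cannot be separated here. The values were used on their deposited scale, to which all differences are relative; how that scale was set between arrays is not stated beyond these notes.

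The log2 values were computed here as log2(deposited intensity + 16), which damps noise at low intensity and understates the change of dim genes. Of 18952 probe sets, 183 control probe sets were left out; of the other 18769, 13647 had 1 gene symbol in the platform's annotation, 402 had several and 4720 were unnamed here. Symbols were looked up through their Entrez identifiers in the RefSeq table of the Release 6 assembly, where 13544 probe sets matched and 0 symbols changed. The probe set with the highest mean stood for each of 11982 genes, 1094 of which had several. Single probe sets were compared for bol, Taf12L, topi, CycB and ovo only. Of these, bol and Taf12L had several, which disagreed. No probe set was filtered for low intensity, and the depth of an array has no count, so its precision rests on the 3 arrays per genotype.

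All 12 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3) with a mean per genotype and no covariate, followed by eBayes, 6 pairwise comparisons and an F test over the 4 genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes with a fold of at least 2; the F test had no fold minimum. Lists of genes were tested with camera in limma, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 186 tests (31 lists in 6 comparisons). The lists were genotype genes, tMAC complex, testis TAFs, general TAFs and TBP, meiotic division regulators, spermatocyte chromatin factors and early transcripts, spermatid differentiation, cup and comet genes, axoneme dyneins and tektins, Y-linked fertility genes, testis mitochondrial paralogs, S-Lap leucyl aminopeptidases, testis and general proteasome subunits, stem cell and spermatogonia genes, piRNA pathway, DNA replication, mitotic regulators, Polycomb repressive complex 2, Polycomb repressive complex 1 and PhoRC, trithorax group, ribosomal proteins, heat shock genes, antimicrobial peptides, and markers of hub, cyst, testis muscle, accessory gland, seminal vesicle with ejaculatory duct, fat body and hemocytes. Genes may sit in several lists, and the marker lists name genes that germ cells can also express. The named genes were fixed by a rule: bam, aly, sa, the tMAC and testis TAF members, twe, bol, CycB, Mst87F, dj, don, fzo, E(z), Su(z)12 and esc whatever their result; the 8 largest differences in each direction among called genes whose arrays did not overlap; and up to 4 members of each list with the largest difference. The symbol don matched no gene here.

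The model was tested on simulated data for 11982 genes: for sa minus bam, aly minus bam, sa minus yw, aly minus yw, bam minus yw and aly minus sa in turn, 98, 98, 100, 98, 100 and 98% of simulated 4-fold and 48, 36, 52, 58, 44 and 42% of 2-fold changes were called, with 0, 0, 1, 2, 1 and 0 false calls. Each gene was drawn independently from a normal distribution with the model's own spread, the same in all genotypes, and 50 genes changed at each fold. These rates therefore hold under the model's assumptions only. In the real arrays the mean SD on the log2 scale ran from 0.126 in aly to 0.22 in yw. Alternatives were quantile normalization, centring each array on the median of all genes or of its ribosomal protein genes, keeping 9714 brighter genes, the mean of a gene's probe sets, every probe set, a fit of the 6 arrays compared, the replicate number as a block, eBayes with trend and robust, array weights, an adjusted p under 0.01, no fold minimum, pseudocounts of 1 and 64, camera with an estimated correlation, fry, and leaving out each array in turn. Chosen after seeing the data were a batch term for replicate 3 and a fit of replicates 1 and 2 alone. Tables were joined in Python 3.11.15 and plots drawn with matplotlib 3.10.9. Scanner files were not used here.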

Results

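Transcript levels were measured in whole testes of 1-day-old Drosophila melanogaster males with Affymetrix Drosophila Genome 2.0 arrays, 1 array per RNA sample. The 12 arrays fell into 4 genotypes of 3 biological replicates each, named by their labels: bam (bam1/bamΔ86), aly (aly2/aly5P), sa (sa1/sa2) and the control y,w, called yw here. Testes mutant for bam fill with germ cells that keep dividing as spermatogonia, whereas testes mutant for aly or sa hold germ cells that arrest as primary spermatocytes. The yw testes run through the whole of spermatogenesis. The gene aly encodes a subunit of tMAC, a testis form of the Myb-MuvB complex, and sa encodes a testis paralog of a TFIID subunit (testis TAF). The deposited values were linear intensities between 9.35 and 25799, with a median over all probe sets of 44.9 to 57.2 per array. All comparisons ran over 11982 genes on log2(intensity + 16), a scale that understates the change of dim genes, and the 3 arrays per genotype limit the precision of every value. Values are mean intensity ± SD (n = 3 arrays), and differences and folds come from that log2 scale in the order given. A gene was called at a limma Benjamini-Hochberg adjusted p below 0.05 with a change of at least 2-fold.

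Among the 4 genotypes, 10030 of 11982 genes (83.7%) differed by limma's F test. The first principal component held 69.4% of the variance and ordered the genotypes as bam, aly, sa and yw, and the second held 21.6% and set the arrays labelled aly against those labelled bam. Across genes, arrays of a genotype correlated at r = 0.977 or more, and the highest r between genotypes was 0.895, between aly and sa; genes are not independent replicates. Levels in single arrays are plotted for 10 transcripts, among them the germline transcription factor ovo, brightest in bam, and the sperm-tail gene Mst87F, brightest in yw.

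**Figure D1:**
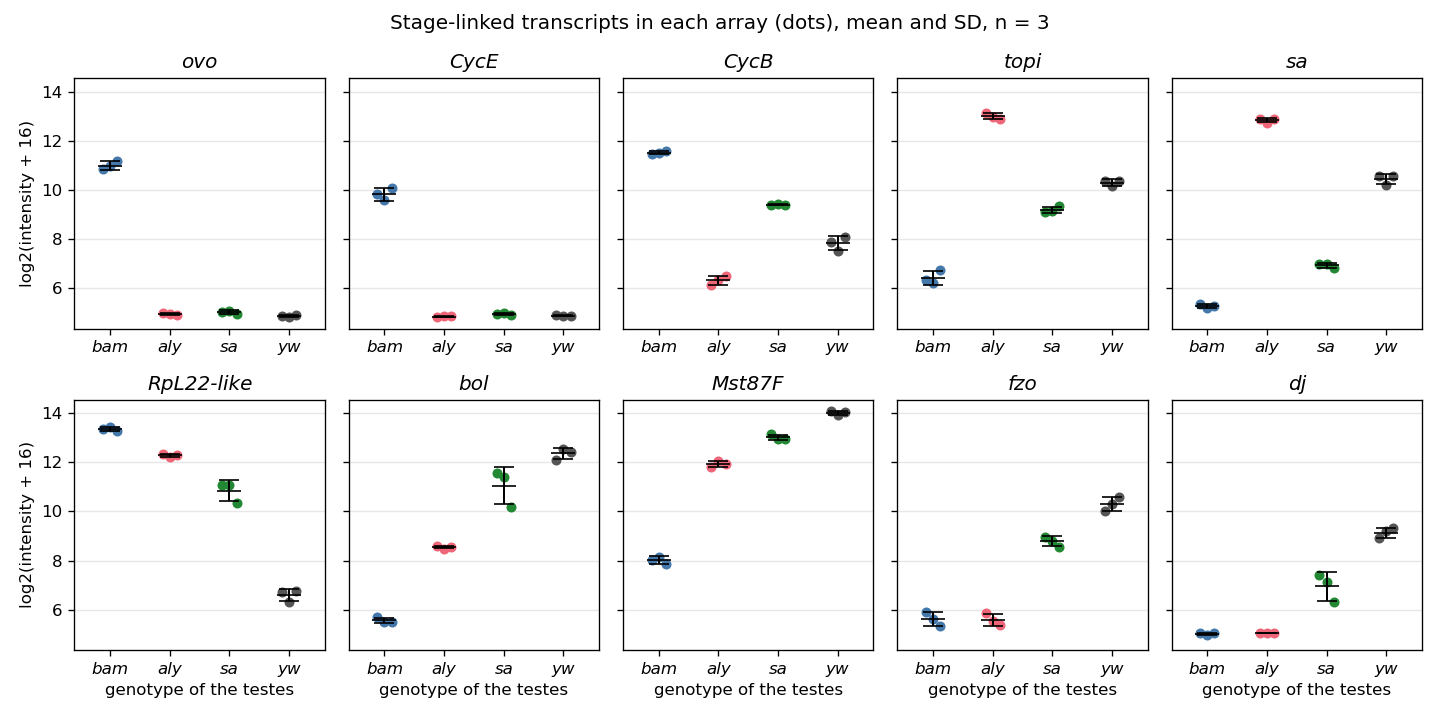
Log2(intensity + 16) of 10 transcripts (panels) in the 12 arrays, by genotype of the testes on the horizontal axis. Dots are single arrays, and bars give the mean and SD of 3 arrays. The ovo values lie near the lower end of the scale outside the bam arrays (mean intensity 2045 in bam and 13.2 in yw), and Mst87F has its highest mean, 16540, in yw.

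The mutated genes were read first as a check of the labels. The sa transcript measured 96.2 to 112 in the 3 arrays labelled sa, 1179 to 1518 in yw, 6878 to 7616 in aly and 20.8 to 25.3 in bam. It was thus lower in its own mutant than in yw (log2 difference -3.52, adjusted p = 8.72e-10). The bam transcript measured 948 to 1174 in the arrays labelled bam, 572 to 651 in aly, 287 to 313 in sa and 36.5 to 67.2 in yw, and was therefore highest in its own mutant. The aly transcript was dim in all arrays, with 58 to 83.3 in bam, 132 to 148 in aly, 107 to 185 in sa and 83.7 to 89.4 in yw. In aly against yw it was higher but missed the fold minimum (log2 difference 0.58, limma adjusted p = 0.00894). Mutant transcripts can persist, and where these probe sets lie relative to the lesions is not known here. Among these only the sa values check a label. The pigmentation gene y, which the control's name y,w marks as mutated, measured 184 ± 27.2 in bam, 158 ± 11.6 in sa and 97.6 ± 4.86 in aly against 43 ± 9.46 in yw; reading it as a label check was chosen after its values were seen. It was called higher than in yw in bam (log2 difference 1.77, with ribosomal centring 0.26 and not called) and sa (1.57, 0.32 and not called) but not in aly (0.96), where it passed with quantile normalization (1.24), median centring (1.04), array weights (1.05), a pseudocount of 1 (1.18) and without yw replicate 2 (1.08), while with ribosomal centring it was -0.23. The labels do not give the y allele of the mutants, and bam, aly, sa and yw below mean arrays labelled so.

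The comparison of sa with bam testes asked which transcripts differ between testes of arrested spermatocytes and testes of dividing spermatogonia-like cells. In sa 19 of 21 spermatid, 12 of 13 cup and comet and 5 of 9 tMAC genes were higher, and 20 of 26 DNA replication, 10 of 16 stem cell (1 higher) and 15 of 24 piRNA genes (1 higher) were lower. These list calls were lost at adjusted p = 0.246 to 0.428 with an estimated correlation. The uncharacterised gene CG1394 was at 17470 ± 476 against 25.7 ± 2.67 in bam (420-fold, adjusted p = 1.09e-13). The gene ocn, a testis gene of the janus cluster, was at 8650 ± 1544 against 21.2 ± 1.75 (230.4-fold). The sperm leucyl aminopeptidase S-Lap7 rose 230.4-fold, the sperm-tail gene Mst84Da 191-fold, and fest, a regulator of cyclin B translation in spermatocytes, 208-fold. In the other direction, ovo was at 16.8 ± 1.54 against 2045 ± 240.3 in bam (62.6-fold lower, adjusted p = 1.46e-12), and CycE, the G1/S cyclin, was 29.3-fold lower.

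Of 21 measured spermatid differentiation genes, 19 were higher in sa, 0 lower and 2 not called, with a median log2 difference of 4.56 (camera adjusted p = 3.40e-09, adjusted p = 0.256 with an estimated correlation). Mst87F rose by 5.0, the spermatid mitofusin fzo by 3.16 and the sperm-tail gene dj by 1.93. The cup and comet genes, transcribed after meiosis in wild-type testes, had 12 of 13 higher (camera adjusted p = 1.29e-06, adjusted p = 0.246 with an estimated correlation), among them boly at 5.50. Testis paralogs of mitochondrial proteins rose in 20 of 22 cases (camera adjusted p = 1.33e-09, adjusted p = 0.245 with an estimated correlation). They were led by ATPsynGL, a paralog of an ATP synthase subunit (6.20), and tomboy20, a paralog of an import receptor (6.05). Testis proteasome paralogs rose in 11 of 13 (camera adjusted p = 6.20e-06, adjusted p = 0.282 with an estimated correlation), with Rpn12R at 5.90, while 12 of 12 general proteasome subunits were not called. Of the S-Lap genes, 4 of 5 were higher (camera adjusted p = 6.58e-04, adjusted p = 0.282 with an estimated correlation). Axoneme genes were higher in 13 of 20 (camera adjusted p = 4.05e-05, adjusted p = 0.245 with an estimated correlation).

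Among regulators of spermatocyte transcription, all 5 testis TAFs were higher in sa than in bam (camera adjusted p = 0.00204, adjusted p = 0.308 with an estimated correlation). The log2 differences were 4.83 for can, 4.20 for nht, 3.39 for Taf12L and, for the mutated sa itself, 1.66, a call lost with a pseudocount of 64 (0.97). Of the tMAC genes, 5 of 9 were higher (camera adjusted p = 0.0118, adjusted p = 0.428 with an estimated correlation), namely wuc (5.18), comr (3.72), topi (2.78), tomb (1.92) and vis (1.67). The spermatocyte chromatin factors and early transcripts were higher in 5 of 7, with 1 lower (camera adjusted p = 0.0132, adjusted p = 0.361 with an estimated correlation), with the testis tubulin betaTub85D at 6.63. The meiotic regulators Rbp4 (5.64) and bol (5.49) rose, whereas CycB fell by 2.12 on the log2 scale and the meiotic Cdc25 phosphatase twe was not called (-0.33, adjusted p = 0.0981). The list as a whole did not pass (camera adjusted p = 0.0825).

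Of 16 stem cell and spermatogonia genes, 10 were lower in sa and 1 higher (camera adjusted p = 7.99e-04, adjusted p = 0.285 with an estimated correlation), with the germline helicase vas at -3.72 and otu at -3.60. The exception, orb2 (4.19), is a translational regulator also used in meiotic cells and spermatids. DNA replication genes were lower in 20 of 26 (camera adjusted p = 1.29e-06, adjusted p = 0.282 with an estimated correlation), such as RnrL (-4.08) and Mcm3 (-4.07). Of the piRNA pathway genes, 15 of 24 were lower and 1 higher (camera adjusted p = 7.99e-04, adjusted p = 0.401 with an estimated correlation), such as piwi (-4.96). Polycomb repressive complex 2 had 4 of 8 lower (camera adjusted p = 0.0357, adjusted p = 0.282 with an estimated correlation), including E(z) (-2.07), Su(z)12 (-1.87) and esc (-2.09). The PhoRC subunit Sfmbt (-4.21) belonged to a list with 5 of 7 lower and 1 higher (camera adjusted p = 0.037, adjusted p = 0.308 with an estimated correlation). In the trithorax group, with trx (-3.67) and kis (-4.04), 7 of 12 were lower and 1 higher (camera adjusted p = 0.0205, adjusted p = 0.256 with an estimated correlation). Of the general TAFs, 5 of 13 were lower, led by Taf4 (-3.62), and the list did not pass (camera adjusted p = 0.215). Markers of other cells moved with these lists, since 9 of 11 testis muscle markers were lower in sa and 1 higher (camera adjusted p = 0.0104, adjusted p = 0.401 with an estimated correlation), with Mlc2 at -3.09 and Actn at -2.92. The mean log2 value of the muscle list was 9.998 to 10.11 in the bam arrays and 7.84 to 8.36 in the sa arrays.

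In all, 4931 genes were called in sa against bam by limma with Benjamini-Hochberg adjustment, 2460 higher and 2471 lower, and 960 of the higher and 203 of the lower ones differed by at least 8-fold. Ribosomal centring moved the list members called higher from 0 to 3 for general TAFs, and median centring those called lower from 2 to 7 for accessory gland markers. Adjusted over the list alone, each list count of this comparison was the same except for the accessory gland markers, which went from 2 lower of 12 to 0. The median difference of all genes, -0.09, was 0.17 with each array centred on its ribosomal protein genes and -0.30 centred on the median of all genes. The bol call rests on 1 of its 3 probe sets, since the other 2 stayed dim, and the Taf12L call on the brighter of 2.

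The comparison of aly with bam put the same question to mutants of a tMAC subunit. All 5 testis TAFs, 6 of 9 tMAC genes, 5 of 7 early spermatocyte genes (1 lower) and 14 of 21 spermatid genes were higher in aly, and CycB was lower. With an estimated correlation none of these lists passed (adjusted p = 0.282 to 0.333). The sa transcript was at 7361 ± 419 against 23 ± 2.23 in bam (189-fold, adjusted p = 1.14e-12), and topi, a tMAC zinc-finger subunit, was at 8263 ± 644 against 71.2 ± 17.2 (96-fold). The bromodomain gene tbrd-2 rose 166-fold, S-Lap2 231-fold, and the sperm-tail gene Mst98Cb 224-fold. CycB, the mitotic and meiotic B-type cyclin, was at 65.1 ± 10.3 against 2940 ± 107 (36.6-fold lower), and ovo was 66.5-fold lower.

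All 5 testis TAFs were higher in aly (camera adjusted p = 2.94e-04, adjusted p = 0.282 with an estimated correlation), with can at 5.79 and nht at 4.74. Of the tMAC genes, 6 of 9 were higher (camera adjusted p = 6.32e-04, adjusted p = 0.333 with an estimated correlation), with wuc at 5.77, comr at 4.62 and vis at 3.77. Spermatocyte chromatin factors and early transcripts were higher in 5 of 7, with 1 lower (camera adjusted p = 0.00704, adjusted p = 0.333 with an estimated correlation), including tbrd-1 (6.40) and betaTub85D (6.97). Among meiotic regulators, 4 of 6 were higher and 2 lower (camera adjusted p = 0.213): Rbp4 (6.29), fest (6.80) and bol (2.99) rose, whereas twe fell by 1.45 on the log2 scale. With the mean of its 3 probe sets the bol difference was 0.77 and no longer a call.

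Of the spermatid genes, 14 of 21 were higher (camera adjusted p = 6.85e-07, adjusted p = 0.282 with an estimated correlation), with ocn at 7.89 and Mst87F at 3.92. Among those that did not pass, dj (0.03) was at 17 ± 0.151 against 16.4 ± 1.14 and fzo (-0.03) at 32.6 ± 8.8 against 33.8 ± 10.1. Cup and comet genes were higher in 6 of 13 (camera adjusted p = 0.00405, adjusted p = 0.322 with an estimated correlation), with hale at 5.47. Axoneme genes were higher in 8 of 20 (camera adjusted p = 0.0041, adjusted p = 0.279 with an estimated correlation). Mitochondrial paralogs were higher in 7 and lower in 1 of 22 (camera adjusted p = 0.00721, adjusted p = 0.402 with an estimated correlation), with ATPsynGL at 6.71. Testis proteasome paralogs rose in 7 of 13 (camera adjusted p = 0.00312, adjusted p = 0.388 with an estimated correlation), with Rpn12R at 6.74. S-Lap genes rose in 4 of 5 (camera adjusted p = 2.94e-04, adjusted p = 0.275 with an estimated correlation). General proteasome subunits passed as a list (camera adjusted p = 0.0346, adjusted p = 0.583 with an estimated correlation) with a median of 0.43, although none of the 12 was called.

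Stem cell and spermatogonia genes were lower in 10 of 16, with 1 higher (camera adjusted p = 3.04e-04, adjusted p = 0.282 with an estimated correlation), with nanos at -4.53. DNA replication genes were lower in 13 of 26 (camera adjusted p = 1.99e-04, adjusted p = 0.361 with an estimated correlation), with CycE at -4.99 and Mcm3 at -3.70. piRNA genes were lower in 15 and higher in 3 of 24 (camera adjusted p = 0.00432, adjusted p = 0.466 with an estimated correlation), with piwi at -4.84. Sfmbt (-3.84) led the Polycomb complex 1 and PhoRC list, with 5 of 7 lower and 1 higher (camera adjusted p = 0.0291, adjusted p = 0.308 with an estimated correlation). The genes kis (-5.12) and trx (-3.77) fell within a trithorax list of 5 lower and 3 higher of 12 that did not pass (camera adjusted p = 0.12). Of Polycomb complex 2, Su(z)12 fell by 1.62 on the log2 scale, E(z) (-0.51) and esc (0.32) were not called, and the list did not pass (camera adjusted p = 0.141). Taf4 was at -3.72, and the general TAFs split into 3 higher and 3 lower of 13 (camera adjusted p = 0.525). In the same arrays 9 of 11 muscle markers were lower (camera adjusted p = 3.04e-04, adjusted p = 0.308 with an estimated correlation), with bt at -4.19 and Mlc2 at -3.76. Accessory gland markers were lower in 11 of 12 (camera adjusted p = 0.0173, adjusted p = 0.601 with an estimated correlation), with the seminal protein gene Acp36DE at -4.39. The mean log2 value of the accessory gland list was 8.36 to 9.09 in the aly arrays and spread over 10.26 to 12.67 in the bam arrays.

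In all, 4195 genes were called, 1953 higher and 2242 lower (46.6% higher), and 496 of the higher and 257 of the lower ones differed by at least 8-fold. Centring each array on its ribosomal protein genes gave 2530 genes higher and 1741 lower (59.2% higher), and centring on the median of all genes gave 2411 genes higher and 1821 lower (57% higher). The median difference of all genes, 0.04, was 0.36 and 0.30 there. No list count of this comparison moved by over 1.5 times and at least 3 genes in another scaling. Adjusted over the list alone, the list counts of this comparison were the same.

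Against the same bam arrays, 1346 genes were higher in both arrest mutants, 1832 lower in both and 20 called in opposite directions. Independent lists of these sizes would share 401 higher and 462 lower genes. Unchanged groups simulated against shared controls shared 0 and 0, which follows because hardly any gene is called in such data. That count does not give the overlap expected of changed lists with shared controls. Across genes the log2 differences correlated at r = 0.783 (simulated 0.5) with a covariance of 2.14 (simulated 0.0173). The simulated covariance is what array noise in the shared bam arrays adds under the model's spread, and the observed covariance lies far above it. Anything else particular to those 3 arrays enters both differences and was not separated here.

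The comparison of sa with yw asked which transcripts differ when a testis TAF is lost, against testes that complete spermatogenesis. Germ cells of sa arrest before the later stages that yw testes hold, so the lost regulator and the stages present cannot be told apart. In sa 15 of 21 spermatid genes were lower, and 3 of 5 testis TAFs and 6 of 9 tMAC genes were higher, each with 1 lower, but with ribosomal centring 1 and 0 were called higher. The testis TAF list did not pass (camera adjusted p = 0.283), and the other 2 did not with an estimated correlation (adjusted p = 0.256 for spermatid and 0.501 for tMAC genes). The uncharacterised gene CG10317 was at 93.7 ± 62.2 against 7092 ± 770.4 in yw (71.2-fold lower, adjusted p = 9.97e-09), and the post-meiotic gene t-cup at 35.5 ± 21.3 against 3039 ± 275 (62.3-fold lower). The protamine genes ProtA and ProtB were 9.38-fold and 18.2-fold lower, and Tpl94D, which encodes a spermatid transition protein, 8.78-fold. RpL22-like, a germline ribosomal protein paralog, was at 1866 ± 501 against 81.9 ± 15.6 (18.9-fold higher), and CCHa1, a neuropeptide gene, rose 20.6-fold.

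Of the spermatid genes, 15 of 21 were lower in sa and none was higher (camera adjusted p = 6.54e-09, adjusted p = 0.256 with an estimated correlation), with Mst36Fa at -4.82, dj at -2.19 and fzo at -1.51. Mst87F just missed the fold minimum (-0.996, adjusted p = 4.72e-06), and was past it with array weights (-1.06), with either centring and without sa replicate 1 (-1.06) or yw replicate 2 (-1.04). Cup and comet genes were lower in 11 of 13 (camera adjusted p = 5.04e-07, adjusted p = 0.245 with an estimated correlation). Axoneme genes were lower in 12 of 20 (camera adjusted p = 1.72e-06, adjusted p = 0.245 with an estimated correlation), with Dnah3 at -3.71. Y-linked fertility genes were lower in 6 of 7 (camera adjusted p = 0.00216, adjusted p = 0.302 with an estimated correlation), with Pp1-Y2 at -2.54 and ARY at -2.31. Mitochondrial paralogs were lower in 17 and higher in 2 of 22 (camera adjusted p = 2.77e-07, adjusted p = 0.256 with an estimated correlation), with COX6AL2 at -5.07. Testis proteasome paralogs were lower in 8 of 13 (camera adjusted p = 0.00108, adjusted p = 0.361 with an estimated correlation), with Prosalpha4T1 at -3.01 and Prosalpha3T at -2.72. S-Lap genes were lower in 2 of 5 (camera adjusted p = 0.00362, adjusted p = 0.308 with an estimated correlation).

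The tMAC list was higher in 6 and lower in 1 of 9 (camera adjusted p = 0.0385, adjusted p = 0.501 with an estimated correlation). The lower one was topi (-1.10), and tomb (1.94) and comr (1.84) were among the higher ones. Of the testis TAFs, Taf12L (2.27), nht (1.98) and mia (1.49) rose, can was not called (0.79), sa itself fell, and the list did not pass (camera adjusted p = 0.283). In replicates 1 and 2 alone can was called (1.1). Centred on ribosomal protein genes, the tMAC list had 0 higher and 1 lower, with a median of 0.29 against 1.54, and the testis TAFs 1 and 1, with a median of 0.24 against 1.49. There tomb (0.69), comr (0.59), nht (0.73) and mia (0.24) were no longer called, and with the mean of 2 probe sets Taf12L was at 0.91. Rbp4 rose (2.38), bol fell by 1.31 on the log2 scale, CycB rose by 1.57, and twe did not pass (0.22). The bol call was lost without sa replicate 3 (-0.88), in replicates 1 and 2 alone (-0.84) and with the mean of its probe sets (-0.42), and the CycB call with ribosomal centring (0.32). Neither the meiotic list (camera adjusted p = 0.572) nor the early spermatocyte list, with 1 higher and 2 lower of 7 (camera adjusted p = 0.707), passed. The latter's median of 0.33 and mean of -0.26 differ in sign, and the median turned negative in the quantile (-0.08), median (-0.06) and ribosomal (-0.92) scalings.

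Ribosomal protein genes were higher in sa in 34 of 41, with 3 lower (camera adjusted p = 1.27e-07, adjusted p = 0.361 with an estimated correlation), with a median of 1.28 that ribosomal centring takes to 0.04 by construction. The paralogs RpL10Aa (-3.17) and RpS28a (-3.41) were lower. General proteasome subunits were higher in 8 of 12 (camera adjusted p = 1.27e-04, adjusted p = 0.361 with an estimated correlation), with Prosbeta2 at 2.36 and a list median of 1.22 that turned to -0.03 with ribosomal centring. General TAFs were higher in 7 of 13 (camera adjusted p = 0.00561, adjusted p = 0.308 with an estimated correlation), led by Taf6 (2.96), and their median of 1.08 turned to -0.17 in that scaling. DNA replication genes rose in 13 of 26 (camera adjusted p = 0.00216, adjusted p = 0.401 with an estimated correlation), with Mcm5 at 2.42 and PCNA at 2.25, and a median of 1.07 that turned to -0.17. Mitotic regulators rose in 11 of 18 (camera adjusted p = 1.27e-04, adjusted p = 0.361 with an estimated correlation), with the separase gene thr at 2.96 and the checkpoint gene Bub3 at 2.89, and kept a positive median in each scaling. piRNA genes were higher in 13 of 24, with 1 lower (camera adjusted p = 0.00748, adjusted p = 0.49 with an estimated correlation; median 1.2, with ribosomal centring -0.04). The stem cell list did not pass (camera adjusted p = 0.128). Its members Phf7 (2.36) and bam (2.17) were among 5 higher, against 1 lower, while the list median of 0.72 turned to -0.53. Polycomb complex 2 was higher in 6 of 8 (camera adjusted p = 0.022, adjusted p = 0.256 with an estimated correlation), with Su(z)12 at 1.53, esc at 1.24 and E(z) not called (0.22), and a list median of 1.47. With ribosomal centring that median was 0.22, with 0 higher and 1 lower. The esc call was lost without sa replicate 3 (0.96), with array weights (0.98) and with median centring (0.84), and its difference turned to -0.01 with ribosomal centring, where Su(z)12 (0.28) and bam (0.92) were not called. Trithorax genes were higher in 6 of 12 (camera adjusted p = 0.0106, adjusted p = 0.246 with an estimated correlation; median 1.02, with ribosomal centring -0.23). In addition, 4 of 7 Polycomb complex 1 and PhoRC genes were higher in a list that did not pass (camera adjusted p = 0.0824), whose median turned from 1.10 to -0.15. Of 4 measured genotype genes (bam, aly, sa and the pigmentation gene y), 2 were higher and 1 lower (camera adjusted p = 0.646), with a median of 1.09 that turned to -0.16 in that scaling.

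Muscle markers were lower in 2 of 11 (camera adjusted p = 0.296), and no accessory gland marker was called of 12 (camera adjusted p = 0.339), a list whose mean ran from 9.44 to 12.12 over the yw arrays. In all, limma called 4409 genes in sa against yw, 2861 higher and 1548 lower (64.9% higher), with 32 higher and 419 lower by at least 8-fold. The split depends on the scale set between arrays. Ribosomal centring called 7068 genes, 369 genes higher and 6699 lower (5.22% higher), with a median of all genes of -1.17 against 0.08. Centring on the median of all genes gave 1791 genes higher and 2020 lower (47% higher), with a median of -0.31. By list, ribosomal centring moved the members called higher from 8 to 1 for general proteasome subunits, 5 to 1 for stem cell genes, 13 to 2 for piRNA genes, 13 to 2 for DNA replication genes, 11 to 5 for mitotic regulators, 4 to 1 for Polycomb complex 1 and PhoRC, 6 to 0 for trithorax genes, 34 to 2 for ribosomal protein genes and 7 to 2 for general TAFs. Those called lower went from 12 to 19 for axoneme genes, 2 to 5 for S-Lap genes, 1 to 6 for stem cell genes, 1 to 6 for piRNA genes, 0 to 6 for DNA replication genes, 2 to 9 for muscle markers, 0 to 10 for accessory gland markers and 1 to 4 for meiotic regulators. With median centring the higher calls went from 8 to 5 for general proteasome subunits, 4 to 1 for Polycomb complex 1 and PhoRC, 34 to 15 for ribosomal protein genes and 7 to 4 for general TAFs, and the lower calls from 2 to 5 for S-Lap genes. Adjusted over the list alone, the list counts of this comparison were the same.

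The comparison of aly with yw asked the same of a tMAC subunit. Here too the lost regulator and the germ cell stages present cannot be told apart. In aly 15 of 21 spermatid, 10 of 13 cup and comet and 14 of 20 axoneme genes and 18 of 22 mitochondrial paralogs (2 higher) were lower. All 5 testis TAFs, 8 of 9 tMAC, 20 of 26 DNA replication and 7 of 8 Polycomb complex 2 genes were higher, and with ribosomal centring 3, 5, 14 and 2. All these list calls were lost at adjusted p = 0.245 to 0.401 with an estimated correlation. CG12860, an uncharacterised gene, was at 45.6 ± 23.4 against 15750 ± 528 in yw (267-fold lower, adjusted p = 1.95e-11). The cup gene w-cup was at 26.1 ± 3.74 against 9387 ± 1177 (223-fold lower) and robl62A, a dynein light chain gene, at 40.3 ± 8.37 against 12740 ± 525. Mst77F, which encodes a sperm chromatin protein, was 79.3-fold lower and ProtB 71.6-fold lower. RpL22-like was at 4983 ± 240 against 81.9 ± 15.6 (51.5-fold higher), Mcm5, a subunit of the replicative helicase, rose 20.6-fold, and Bap60, a Brahma complex subunit, 19.3-fold.

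Spermatid genes were lower in 15 of 21 (camera adjusted p = 6.54e-09, adjusted p = 0.256 with an estimated correlation), with djl at -6.54, fzo at -4.70, dj at -4.09 and Mst87F at -2.08. Cup and comet genes were lower in 10 of 13 (camera adjusted p = 4.95e-07, adjusted p = 0.245 with an estimated correlation), with t-cup at -6.52 and c-cup at -6.38. Axoneme genes were lower in 14 of 20 (camera adjusted p = 7.08e-07, adjusted p = 0.245 with an estimated correlation), with Tektin-A at -6.67 and Dnali1 at -6.24. Mitochondrial paralogs were lower in 18 and higher in 2 of 22 (camera adjusted p = 8.11e-09, adjusted p = 0.246 with an estimated correlation), with COX5BL at -7.66, tomboy20 at -7.25 and ttm3 at -7.04. Testis proteasome paralogs were lower in 8 and higher in 2 of 13 (camera adjusted p = 0.00185, adjusted p = 0.361 with an estimated correlation), with Prosalpha6T at -6.80 and Prosbeta5R1 at -6.75. General subunits were higher in 9 of 12 (camera adjusted p = 7.99e-04, adjusted p = 0.401 with an estimated correlation), with Prosbeta2 at 2.60. S-Lap genes were lower in 3 of 5 (camera adjusted p = 0.0106, adjusted p = 0.361 with an estimated correlation), led by S-Lap5 (-5.08). Y-linked fertility genes were lower in 6 of 7 (camera adjusted p = 0.0015, adjusted p = 0.282 with an estimated correlation), led by Pp1-Y2 (-4.68).

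All 5 testis TAFs were higher in aly (camera adjusted p = 0.0203, adjusted p = 0.401 with an estimated correlation): mia (2.65), nht (2.52), sa (2.38), can (1.75) and Taf12L (1.07). The Taf12L call was lost with the mean of its probe sets (0.49) and without yw replicate 2 (0.95), its difference turned to -0.12 with ribosomal centring, and can was not called there (0.56). Of the tMAC genes 8 of 9 were higher (camera adjusted p = 0.00373, adjusted p = 0.377 with an estimated correlation), with tomb (3.21), vis (2.88), comr (2.75) and topi (2.70) first, and aly the one not called. Rbp4 rose (3.02), bol (-3.81) and CycB (-1.51) fell, and twe missed the fold minimum (-0.89, adjusted p = 5.24e-04), which it passed without yw replicate 2 (-1.10), with array weights (-1.03) and with ribosomal centring (-2.08). The meiotic list did not pass (camera adjusted p = 0.21). The early spermatocyte list, 3 higher and 2 lower of 7, did not pass either (camera adjusted p = 0.605), and its median of 0.95 turned to -0.24 with ribosomal centring.

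DNA replication genes were higher in 20 of 26 (camera adjusted p = 6.92e-05, adjusted p = 0.333 with an estimated correlation), with Orc2 at 3.92. Mitotic regulators were higher in 13 of 18, with 1 lower (camera adjusted p = 0.00312, adjusted p = 0.466 with an estimated correlation). Polycomb complex 2 was higher in 7 of 8 (camera adjusted p = 0.0163, adjusted p = 0.256 with an estimated correlation), with esc at 3.65, E(z) at 1.78 and Su(z)12 at 1.77. Of these, E(z) (0.59) and Su(z)12 (0.58) were not called with ribosomal centring. Trithorax genes were higher in 8 of 12 (camera adjusted p = 0.024, adjusted p = 0.256 with an estimated correlation), with mod(mdg4) at 2.83. By contrast, 4 of 7 Polycomb complex 1 and PhoRC genes were higher in a list that did not pass (camera adjusted p = 0.13). piRNA genes were higher in 15 of 24, with 1 lower (camera adjusted p = 0.0186, adjusted p = 0.537 with an estimated correlation). General TAFs were higher in 8 of 13 (camera adjusted p = 0.0211, adjusted p = 0.361 with an estimated correlation). Of the stem cell list, bam (3.17), Phf7 (2.86) and zpg (2.73) were among 6 higher, against 1 lower, but the list did not pass (camera adjusted p = 0.371), and its median of 0.39 turned to -0.80 with ribosomal centring. Ribosomal protein genes were higher in 31 of 41, with 3 lower (camera adjusted p = 1.36e-05, adjusted p = 0.429 with an estimated correlation), and RpL10Aa was 162-fold lower, at 33 ± 4.94 against 7974 ± 1571. Accessory gland markers moved with aly too, 4 of 12 lower (camera adjusted p = 0.0299, adjusted p = 0.657 with an estimated correlation), from a list mean of 9.44 to 12.12 over the yw arrays and 8.36 to 9.09 over the aly arrays. Of the others, 2 of 11 muscle markers were lower (camera adjusted p = 0.128).

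In all, limma called 5188 genes, 3385 higher and 1803 lower (65.2% higher), with 295 higher and 1104 lower by at least 8-fold. Ribosomal centring gave 1149 genes higher and 6253 lower (15.5% higher), with a median of all genes of -1.04 against 0.15. In that scaling the list members called higher went from 9 to 4 for general proteasome subunits, 6 to 3 for stem cell genes, 15 to 7 for piRNA genes, 13 to 7 for mitotic regulators, 4 to 1 for Polycomb complex 1 and PhoRC, 8 to 3 for trithorax genes and 31 to 2 for ribosomal protein genes, and those called lower from 1 to 8 for stem cell genes, 1 to 5 for piRNA genes, 0 to 3 for DNA replication genes, 0 to 3 for trithorax genes, 2 to 9 for muscle markers and 4 to 12 for accessory gland markers. Adjusted over the list alone, the accessory gland count fell from 4 to 1 lower, and the other list counts were the same.

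Against the same yw arrays, 1400 genes were lower in both arrest mutants, 2409 higher in both and 18 called in opposite directions. Independent lists of these sizes would share 233 lower and 808 higher genes. Groups simulated without any change against the same controls shared 0 and 0. Here too hardly any gene is called in such data, so this is no test of the overlap. The differences correlated across genes at r = 0.87 (simulated 0.5), with a covariance of 2.34 (simulated 0.0172). The simulated covariance is what array noise in the shared yw arrays adds under the model's spread, far below the observed covariance. Anything else particular to the 3 yw arrays enters both differences and was not separated here. Ribosomal centring takes the genes lower in both to 5538. Of the 1400 genes, 914 were lower still in aly than in sa and 19 higher, with a median aly minus sa difference of -1.79.

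**Figure D2:**
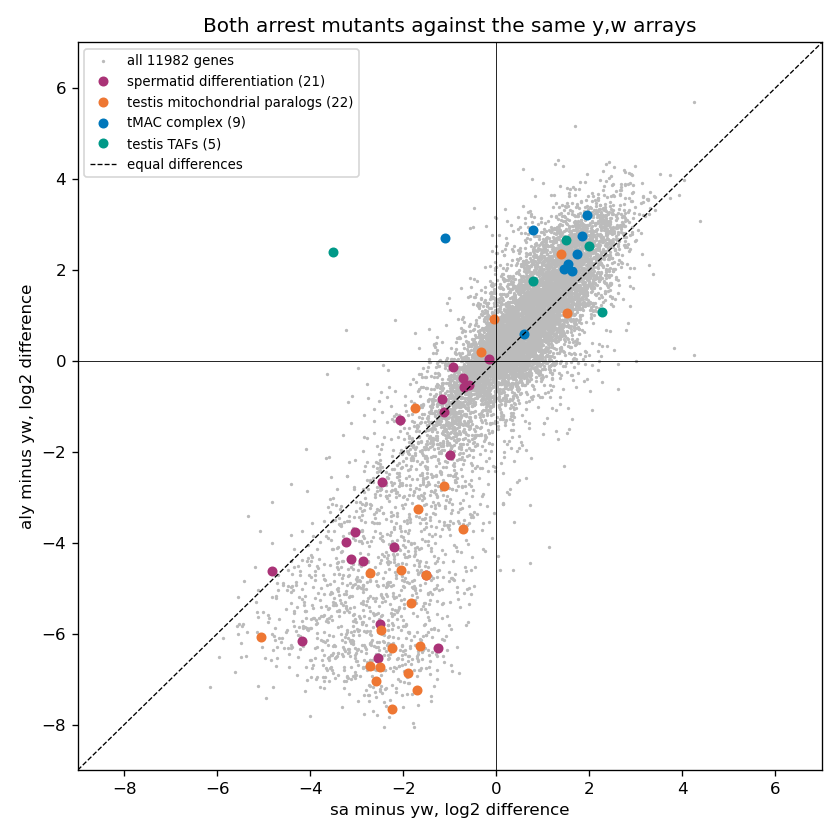
Log2 difference from yw of each of the 11982 genes in sa (horizontal axis) and aly (vertical axis), with 4 gene lists in colour and a dashed line of equal differences. Mitochondrial paralogs have a median of -5.02 in aly and -1.79 in sa, and both stayed negative in every scaling tried, with -6.21 and -3.04 under ribosomal centring, while the testis TAFs have medians of 2.38 and 1.49, which that centring takes to 1.2 and 0.24.

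The comparison of bam with yw set testes held at the spermatogonial stage against the complete lineage. In bam 20 of 21 spermatid, 13 of 13 cup and comet and 17 of 20 axoneme genes were lower, and 13 of 16 stem cell (1 lower), 21 of 24 piRNA (2 lower) and 23 of 26 DNA replication genes were higher. None of these list calls held with an estimated correlation (adjusted p = 0.245 to 0.414). S-Lap7 was at 22.1 ± 1.98 against 17010 ± 984 in yw (447-fold lower, adjusted p = 2.04e-13). The tubulin betaTub85D was at 30.4 ± 5.54 against 15650 ± 764 (339-fold lower) and the uncharacterised gene CG17376 was 443-fold lower. RpL22-like was at 10480 ± 648 against 81.9 ± 15.6 (108-fold higher), ovo rose 70.2-fold, piwi 54-fold and Phf7, a histone reader of the male germline, 43.4-fold.

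Spermatid genes were lower in 20 of 21 (camera adjusted p = 3.52e-11, adjusted p = 0.246 with an estimated correlation), with Mst84Db at -8.44, ocn at -8.43, Mst87F at -6.0, fzo at -4.67 and dj at -4.12. All 13 cup and comet genes were lower (camera adjusted p = 3.20e-08, adjusted p = 0.245 with an estimated correlation). Axoneme genes were lower in 17 of 20 (camera adjusted p = 1.28e-08, adjusted p = 0.245 with an estimated correlation), with Tektin-A at -7.09. Y-linked genes were lower in 6 of 7 (camera adjusted p = 0.00425, adjusted p = 0.308 with an estimated correlation), with Pp1-Y2 at -4.75. Mitochondrial paralogs were lower in 20 of 22, with 1 higher (camera adjusted p = 8.83e-11, adjusted p = 0.245 with an estimated correlation), with COX5BL at -7.83. Testis proteasome paralogs were lower in 10 of 13 (camera adjusted p = 5.12e-06, adjusted p = 0.282 with an estimated correlation), with Prosalpha6T at -6.90. S-Lap genes were lower in 4 of 5 (camera adjusted p = 2.94e-04, adjusted p = 0.275 with an estimated correlation). Of the testis TAFs 4 of 5 were lower (camera adjusted p = 0.0224, adjusted p = 0.401 with an estimated correlation), with sa at -5.18 and can at -4.04. The tMAC list, 2 higher and 3 lower of 9, did not pass (camera adjusted p = 0.348). Of its members, topi (-3.88) and wuc (-3.65) were lower, Caf1-55, which also serves other chromatin complexes, was higher (2.43), and aly was not called (-0.33, with ribosomal centring -1.83 and called). Early spermatocyte genes were lower in 5 of 7, with 1 higher (camera adjusted p = 0.0163, adjusted p = 0.361 with an estimated correlation), the exception being Nxt1, an mRNA export factor (4.65). Among meiotic regulators 4 of 6 were lower, with fest at -7.64 and bol at -6.80, CycB was higher (3.69) and twe was not called (0.56), and the list did not pass (camera adjusted p = 0.0931).

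Stem cell and spermatogonia genes were higher in 13 of 16, with 1 lower (camera adjusted p = 0.00265, adjusted p = 0.308 with an estimated correlation), with zpg, a germline gap junction gene, at 5.37 and bam at 3.93. The lower one was orb2 (-6.25). piRNA genes were higher in 21 of 24, with 2 lower (camera adjusted p = 0.00161, adjusted p = 0.414 with an estimated correlation). DNA replication genes were higher in 23 of 26 (camera adjusted p = 1.37e-06, adjusted p = 0.282 with an estimated correlation), with Mcm3 at 5.23, Mcm5 at 5.04 and CycE at 4.95. Mitotic regulators were higher in 12 of 18 (camera adjusted p = 0.00748, adjusted p = 0.501 with an estimated correlation). All 8 Polycomb complex 2 genes were higher (camera adjusted p = 0.0107, adjusted p = 0.246 with an estimated correlation), with Jarid2 at 3.45, Su(z)12 at 3.40, esc at 3.33 and E(z) at 2.29. All 7 of Polycomb complex 1 and PhoRC were higher (camera adjusted p = 0.0186, adjusted p = 0.282 with an estimated correlation), with Sfmbt at 5.19. Trithorax genes were higher in 10 of 12 (camera adjusted p = 0.00288, adjusted p = 0.245 with an estimated correlation), with kis at 5.17 and trx at 3.89. With ribosomal centring E(z) (0.78) and Caf1-55 (0.92) were not called. General TAFs were higher in 10 of 13 (camera adjusted p = 0.00748, adjusted p = 0.308 with an estimated correlation), with Taf4 at 4.08. General proteasome subunits were higher in 5 of 12 (camera adjusted p = 0.0104, adjusted p = 0.501 with an estimated correlation), whose median of 0.81 turned to -0.70 with ribosomal centring. Ribosomal protein genes were higher in 36 of 41, with 3 lower (camera adjusted p = 1.23e-05, adjusted p = 0.428 with an estimated correlation), and that centring takes their median of 1.5 to -0.01 by construction. Markers of other cells moved with these lists, since 9 of 11 muscle markers were higher in bam and 2 lower (camera adjusted p = 0.142), with Mlc2 at 3.67 and Actn at 3.11. Similarly, 4 of 9 cyst cell markers were higher (camera adjusted p = 0.355), with puc at 3.50, although the cyst median of 0.58 turned to -0.93 with ribosomal centring. The muscle list had a mean of 9.998 to 10.11 in the bam arrays and 8.13 to 8.79 in the yw arrays.

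In all, limma called 6319 genes, 4099 higher and 2220 lower (64.9% higher), with 645 higher and 1496 lower by at least 8-fold. Ribosomal centring gave 1205 genes higher and 6733 lower (15.2% higher), with a median of all genes of -1.32 against 0.18, and 0.001 with median centring. By list, that centring took the members called higher from 5 to 0 for general proteasome subunits, 21 to 13 for piRNA genes, 12 to 6 for mitotic regulators, 8 to 3 for Polycomb complex 2, 7 to 3 for Polycomb complex 1 and PhoRC, 9 to 4 for muscle markers, 36 to 4 for ribosomal protein genes and 10 to 5 for general TAFs, and those called lower from 0 to 3 for general proteasome subunits, 0 to 4 for mitotic regulators, 0 to 4 for cyst cell markers and 3 to 6 for tMAC genes. Adjusted over the list alone, the list counts of this comparison were the same.

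**Figure D3:**
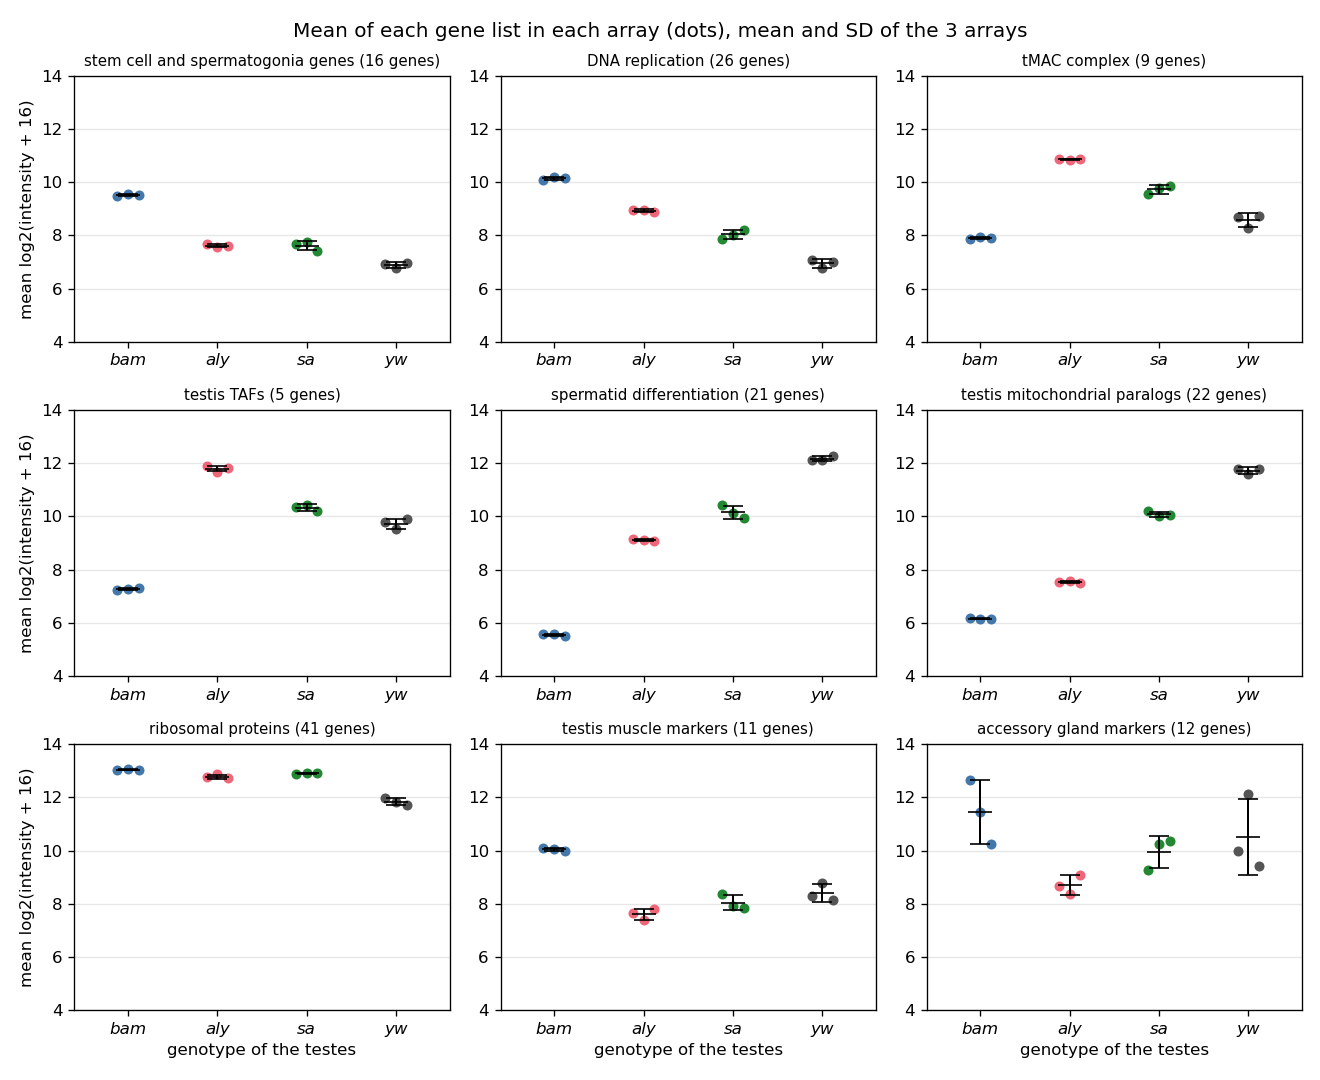
Mean log2(intensity + 16) of 9 gene lists (panels, with the number of measured genes) in the 12 arrays, by genotype of the testes on the horizontal axis. Dots are single arrays and bars the mean and SD of 3 arrays. The spermatid list runs from 5.49 to 5.57 in bam to 12.12 to 12.29 in yw, and the accessory gland list spreads over 9.44 to 12.12 within yw alone.

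The comparison of the arrest mutants with each other asked which transcripts differ between testes without a tMAC subunit and testes without a testis TAF. Here too the lost regulator cannot be told apart from other differences between the genotypes, such as the cells present or the strain background. In aly 3 of 9 tMAC and 12 of 26 DNA replication genes were higher, and 17 of 22 mitochondrial paralogs, 9 of 21 spermatid and 7 of 13 cup and comet genes (1 higher) were lower. Each of these lists lost its call with an estimated correlation (adjusted p = 0.246 to 0.49). The sa transcript was at 7361 ± 419 against 107 ± 9.26 (60.1-fold higher in aly, adjusted p = 2.56e-11). The tMAC gene topi was at 8263 ± 644 against 575 ± 53.6 (14-fold) and tbrd-2 at 6990 ± 1583 against 629.7 ± 152 (10.9-fold). Mst77F was at 199 ± 27.7 against 7164 ± 1528 (33.1-fold lower in aly), tomboy20 was 46.5-fold lower, and CycB, at 65.1 ± 10.3 against 665 ± 9.03, was 8.45-fold lower. The uncharacterised genes CG9016 (78.2-fold lower) and CG7907 (14.2-fold higher) were among the most changed.

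Of the tMAC genes 3 of 9 were higher in aly and none was lower (camera adjusted p = 0.00851, adjusted p = 0.407 with an estimated correlation), with vis at 2.09 and tomb at 1.27, and comr (0.90) and wuc (0.58) not called. Of the testis TAFs, mia (1.17) was higher, as was sa, the gene mutated in the sa arrays, and Taf12L was lower (-1.20). Both can (0.95, limma adjusted p = 7.59e-04) and nht (0.54, limma adjusted p = 0.00251) were higher but missed the fold minimum. The testis TAFs did not pass as a list (camera adjusted p = 0.0951). Centred on the median of all genes, 7 of 9 tMAC genes were called higher, with a list median of 1.09 against 0.61, and 4 of 5 testis TAFs, with none lower. There comr (1.38), wuc (1.06), can (1.44) and nht (1.02) were called and Taf12L (-0.72) was not. Likewise can passed without aly replicate 2 (1.09) or sa replicate 2 (1.07), and comr without sa replicate 3 (1.00). Of the early spermatocyte list 2 were higher, with tbrd-1 at 2.11, and 1 lower, and the list did not pass (camera adjusted p = 0.152). DNA replication genes were higher in 12 of 26 (camera adjusted p = 3.55e-04, adjusted p = 0.361 with an estimated correlation), with Orc2 at 2.12 and Mcm5 at 1.95. Of Polycomb complex 2, esc (2.41) and E(z) (1.56) were higher in aly and Su(z)12 was not called (0.24), and the list did not pass (camera adjusted p = 0.236). The general TAFs did not pass as a list (camera adjusted p = 0.525), although Taf1 rose (2.28).

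Spermatid genes were lower in aly in 9 of 21 (camera adjusted p = 0.00981, adjusted p = 0.49 with an estimated correlation), with djl at -4.00, Pif1A at -3.28, fzo at -3.19, dj at -1.90 and Mst87F at -1.08, the last not called with median centring (-0.60). Mitochondrial paralogs were lower in 17 of 22 and none was higher (camera adjusted p = 2.75e-08, adjusted p = 0.246 with an estimated correlation), with COX5BL at -5.42 and ATPsynCF6L at -4.96. Cup and comet genes were lower in 7 and higher in 1 of 13 (camera adjusted p = 0.00287, adjusted p = 0.308 with an estimated correlation), with c-cup at -4.01 and w-cup at -3.80. Testis proteasome paralogs were lower in 6 and higher in 2 of 13 (camera adjusted p = 0.0299, adjusted p = 0.501 with an estimated correlation), with Prosbeta5R1 at -5.12. Axoneme genes were lower in 8 and higher in 1 of 20 (camera adjusted p = 0.0173, adjusted p = 0.308 with an estimated correlation), with Tektin-A at -4.83 and a median of -0.10 that turned to 0.38 with median centring. The S-Lap list did not pass (camera adjusted p = 0.824): S-Lap5 was lower (-4.22), and the list's median of 0.49 and mean of -0.81 differ in sign. Among meiotic regulators CycB, bol (-2.50) and twe (-1.11) were lower in aly in a list that did not pass (camera adjusted p = 0.0797). The twe call was lost with quantile (-0.65) and median (-0.64) scaling and a pseudocount of 64 (-0.79), and with the mean of probe sets bol (-0.81) and Taf12L (-0.42) were not called. The Y-linked list did not pass (camera adjusted p = 0.157), and its median of -0.28 turned to 0.20 with median centring. Accessory gland markers were lower in aly in 1 of 12 (camera adjusted p = 0.109), a call of Acp36DE (-2.61) that was lost without aly replicate 2 (-2.12) or sa replicate 2 (-2.37). The muscle median of -0.35 turned to 0.13 with median centring.

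In all, limma called 2373 genes, 946 higher and 1427 lower in aly (39.9% higher), with 17 higher and 445 lower by at least 8-fold. Centring on the median of all genes gave 2395 genes higher and 1039 lower (69.7% higher), with a median of all genes of 0.57 against 0.10. Quantile normalization gave 1331 genes higher and 1263 lower (51.3% higher). Median centring moved the list members called higher from 0 to 3 for mitochondrial paralogs, 4 to 10 for piRNA genes, 1 to 5 for mitotic regulators and 2 to 7 for trithorax genes. Adjusted over the list alone, the accessory gland count went from 1 to 0 lower and the muscle count from 2 to 1 lower of 11, and the other list counts were the same.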

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

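The alternatives were chosen before the data were examined, except the batch term and the fit of replicates 1 and 2, tests chosen only after the result was seen. Leaving out 1 array at a time gave 4820 to 5015 genes for sa minus bam, 4121 to 4258 for aly minus bam, 4283 to 4527 for sa minus yw, 5048 to 5266 for aly minus yw, 6306 to 6346 for bam minus yw and 2163 to 2658 for aly minus sa, with 9647 to 10166 by the F test, 1376 to 1457 lower in both arrest mutants and 93 to 97 of 186 list tests passing. With no fold minimum the counts were 8101 for sa minus bam, 7064 for aly minus bam, 7761 for sa minus yw and 6320 for aly minus sa, which follows from the wider threshold. Centring on ribosomal protein genes moved sa minus yw to 7068 genes, of which 1917 were also called without it, and the genes lower in both to 5538; this setting takes the higher level of those genes in the mutants as the scale, which lowers all other genes against yw. It also reversed esc in sa minus yw (-0.011) and Taf12L in aly minus yw (-0.12), by the same shift. The list tests that passed, 95 of 186, were 0 with an estimated correlation (lowest adjusted p = 0.245, 31 at an unadjusted p under 0.05 by camera), 153 by fry and 172 by its mixed test, which ask different questions. The other planned settings left each total within 1.5 times its reported value, but counts by direction moved further, since centring shifts all genes of an array alike. Median centring moved the genes higher in aly minus sa from 946 to 2395 and in sa minus yw from 2861 to 1791, and ribosomal centring those in aly minus yw from 3385 to 1149 and in bam minus yw from 4099 to 1205. Of 271 named gene results, the calls lost were 1 with quantile normalization, 4 with median centring, 17 with ribosomal centring besides the 2 reversed, 6 with the mean of probe sets, 2 with array weights, 1 at an adjusted p under 0.01 and 3 with a pseudocount of 64; the cause was not tested. Genes near the lower end of the intensity scale have understated folds. A 2-fold change lies at the fold minimum itself, where 36 to 58% of simulated ones were called. With no fold minimum 88 to 100% of the simulated 2-fold changes passed.

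The replicate numbers in the labels are shared by the genotypes, and a fit with them as a replicate block called 4924, 4176, 4411, 5184, 6316 and 2365 genes in the order above, 9864 by the F test and 1402 lower in both, with 95 list tests passing and no named call changed. Over genes, deviations of same-numbered arrays correlated at r over 0.1 in 1 of 3 pairs in sa minus bam (replicate 2, 0.168), sa minus yw (replicate 2, 0.157), bam minus yw (replicate 3, 0.481) and aly minus sa (replicate 1, 0.203), and in 0 in the others. In the same order 3, 2, 2, 0, 2 and 1 of the 6 arrays correlated best with their own number, so the numbers were not taken to pair the samples. All 21 spike-in and poly-A controls had a higher mean in replicate 3 than in replicates 1 and 2 (1.47 to 5.65 times), and the 9 hybridization controls were brightest in replicate 3 of every genotype. With replicate 3 as a batch term the counts were 4937, 4197, 4413, 5190, 6322 and 2370, and within replicates 1 and 2 alone 5018, 4256, 4512, 5228, 6354 and 2679; replicate 3 alone has 1 array per genotype and no test.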

Other observations

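The tests of the spread among tMAC and testis TAF genes, of the spike-ins and of the somatic markers in bam were chosen only after the result was seen. Ribosomal protein paralogs went opposite ways. RpL22-like was 108-fold higher in bam and 18.9-fold higher in sa than in yw, whereas RpL10Aa was 173-fold lower in bam and 9.01-fold lower in sa, and RpS28-like 69.8-fold and 12-fold lower. Against bam, 2 of 41 ribosomal protein genes were lower in aly (camera adjusted p = 0.0224, adjusted p = 0.687 with an estimated correlation), and the list median of -0.24 turned to 0.03 with median and 0.08 with ribosomal centring. The antimicrobial peptide genes Drs (3.01) and Mtk (2.19, not called with ribosomal centring, 0.69) were higher in bam than in yw. They were 2 of 6 in a list that did not pass (camera adjusted p = 0.378) and whose median of 0.35 turned to -1.15 with ribosomal centring. Of the heat shock genes, 3 of 5 were higher in sa than in yw (camera adjusted p = 0.0854), with the small heat shock gene Hsp26 at 1.94, which was not called with ribosomal centring (0.69). In bam 3 were higher (camera adjusted p = 0.296), and the median of 1.13 turned to -0.37; with ribosomal centring 0 and 0 were called higher.

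Among markers of other cells, collagen IV genes of the hemocyte list were higher in bam than in yw (vkg 3.29, Col4a1 2.73), with 3 of 8 higher (camera adjusted p = 0.213) and a median of 0.82 that turned to -0.68 with ribosomal centring. Fat body markers were lower in aly than in bam in 5 of 8 (camera adjusted p = 0.0346, adjusted p = 0.466 with an estimated correlation), with the lipoprotein gene apolpp at -2.66, which was also 37.2-fold lower in aly than in yw. The 4 fat body markers with the largest difference between sa and bam were lower in sa too. These were Yp3 (-2.43), Fbp1 (-2.04), Lsp2 (-1.79) and Fbp2 (-1.68). Cyst cell markers passed in aly against bam (camera adjusted p = 0.0231, adjusted p = 0.282 with an estimated correlation) with 2 of 9 lower, puc (-3.42) and zfh1 (-2.66). Of 5 seminal vesicle and ejaculatory duct markers, 2 were lower in sa than in bam (camera adjusted p = 0.304), with Dup99B at -4.35. Dup99B was at 116 ± 57.8 in sa against 4483 ± 5687 in bam, so it varied widely between the bam arrays. In sa against yw the list's median of 0.01 and mean of -0.69 differ in sign. Of 5 hub markers, the cadherin gene shg was higher (2.20, not called with ribosomal centring, 0.95) and esg lower (-1.65) in sa than in yw, in a list that did not pass (camera adjusted p = 0.524).

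The first pattern weighed is that tMAC and testis TAF transcripts differ between aly and sa testes. Among 12 members other than aly and sa, topi (3.81) and Taf12L (-1.20) lay 5.01 apart on the log2 scale (standard error 0.188), which argues against 1 scale factor between the arrays. Among the 6 members at least 4-fold above bam in both mutants, the span was the same 5.01, which argues against 1 different share of spermatocytes, as those members would then share 1 difference. The others, comr, wuc, can and nht, lay between 0.54 and 0.95. A common shift of these members stays open, and so does the hypothesis that loss of aly and of sa may change topi and Taf12L differently, which no test here separates from other causes.

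The second is that ribosomal protein transcripts are higher in the mutants than in yw, with medians of 1.5 in bam, 1.30 in aly and 1.28 in sa. A smaller share of RNA that is not sperm specific in yw was predicted to raise markers of somatic cells alike. Their median was -0.208 in aly (SD 1.17, 18 genes) and 0.08 in sa (SD 1.04), so they did not rise with the ribosomal genes there. The share of somatic cells in each genotype is not known here, so these markers cannot decide the question for RNA of germ cells. Many general proteasome, general TAF and DNA replication genes were also called higher in aly and sa. This explanation predicts that, but so would 1 scale factor between arrays or a difference in the germ cell stages present. These genes therefore do not decide between them. In bam the median of the somatic markers was 1.92 (SD 1.83, 12 higher and 2 lower). A smaller share of RNA that is not sperm specific in yw also predicts this, so it may account for part of the bam difference. Hybridization spike-ins were higher than in yw by 0.397 in bam, 0.608 in aly and 0.095 in sa, below the ribosomal medians by less than 2 standard errors in the model without a batch (0.639, 0.6 and 0.633) and by more than 2 with replicate 3, where all of them were brighter, as a batch term (0.165 each); within replicates 1 and 2 they were 0.464, 0.747 and 0.178, and within replicate 3 0.264, 0.331 and -0.07. Given the batch term the hybridization controls argue against 1 scale factor between arrays as the whole cause, although it may account for part in aly and bam. The poly-A controls were not part of this test and spread widely within a genotype. For example, DapX-3 ran from 1274 to 5933 in bam, 979 to 2428 in aly, 571 to 3199 in sa and 230 to 1312 in yw. A factor that acts on the poly-A controls therefore stays open. A difference in the germ cell stages present, which the genotypes name, was not tested.

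The third is that neighbouring genes changed alike between aly and sa: over 10347 adjacent pairs the aly minus sa differences correlated at r = 0.137, above the highest of 1000 permutations of the gene order (0.032; permutation p = 0.001, the smallest they can give). Genes 5 places apart gave r = 0.04 against a highest permuted value of 0.043 (p = 0.002, Benjamini-Hochberg adjusted p = 0.00333 over 20 such values in 2 comparisons; adjacent genes 0.00182); genes are not independent replicates. Genes 2 apart gave r = 0.09 (highest permuted 0.031), and in sa minus bam genes 5 apart gave 0.047 (highest 0.042), which argues against shared signal as the whole cause there, although both comparisons use the same sa arrays. With pairs that share a symbol stem or a probe set of several targets left out, adjacent genes still gave r = 0.149, genes 2 apart 0.094 and genes 5 apart 0.041 (highest permuted values 0.033, 0.037 and 0.04), and in sa minus bam genes 5 apart 0.046 (0.038). In aly minus sa, expression of neighbours together and signal shared by near-identical or overlapping neighbours cannot be told apart, since overlapping genes and paralogs with unlike names remain in these pairs and genes 5 apart lay above every permutation only with pairs left out; the first may be a hypothesis for a test on data with strand and unique reads.

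Each pair of genotypes allows 10 splits of its 6 arrays, too few for a share under 0.05: the real split called 4931 genes for sa minus bam, 4195 genes for aly minus bam, 4409 genes for sa minus yw, 5188 genes for aly minus yw, 6319 genes for bam minus yw and 2373 genes for aly minus sa, and in each comparison it was the 1 split with as many, the highest other calling 0. Of 100 splits of the 12 arrays into 4 groups of 3, the real one included, 1 gave as many genes by the F test as the real 10030. The highest other gave 6736 and 86 gave none. In both kinds of split, the others mix genotypes and so widen the spread within a group. The splits therefore show that the arrays cluster by label, and they do not exclude chance for the genes called.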
